A study of Drosophila melanogaster with 2 samples.

How the data were processed

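The samples were 2 ChIP-seq libraries from mixed-sex whole Drosophila melanogaster embryos aged 0 to 12 h, biological replicates 2 and 4 of a line expressing GFP-tagged Sry-beta. Per the labels, the antibody's target was Sry-β and chromatin was sonicated to 200 to 800 bp. The labels' free text names both libraries an input control, while their assay title, antibody and peak lists are those of a ChIP experiment; they were treated as ChIP libraries.

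The authors deposited 4 peak lists in narrowPeak format on dm6. Per the deposited readme files, each replicate's relaxed list was made from that library's alignment and the same control alignment, the pooled relaxed list from both alignments and that control, and the IDR list from the 3 relaxed lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each relaxed list held 30000 peaks, a fixed length. The signal value of each peak is the authors' own; its scale is not stated, so it was used only to rank or compare peaks within a list. The deposited −log10 q values had a single value, 3.84, in all IDR peaks and were not used for ranking. Peak widths were mostly a single value per list (490 bp in the pooled and IDR lists, 380 bp in replicate 2 and 584 bp in replicate 4), so widths do not measure the extent of binding. Summits that fell past the end of a peak were moved to its last base, in 2 IDR peaks and in 1 to 3 peaks of each relaxed list. The files hold no read counts, so depth is unknown and no interval covers sequencing error; Wilson intervals of shares (95%) cover the number of peaks or genes only.

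Everything else was computed here with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes and TSSs came from Ensembl release 115 and sequence from the release 6 genome assembly; every peak lay within the reference arms. A promoter peak had its summit within 500 bp of a TSS of a protein-coding gene. Summits were placed at random 1000 times on the assembled bases of the same arm. Replicate values came from the N highest peaks of each relaxed list, N being the number of IDR peaks (3257). Random placements gave one-sided p-values for the overlap and the promoter share and two-sided ones for the 7 feature classes. Arms were tested with exact binomial tests and motifs, words, divergent promoters and gene lists with two-sided Fisher's exact tests, each family adjusted by Benjamini-Hochberg with a threshold of 0.05. Medians of signal were compared by permutation. Odds ratios had 0.5 added to each cell.

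Motifs were searched on both strands within 50 bp of each summit and in windows of the same size centred 500 bp on either side. The 13 motifs and 23 gene lists were written from general knowledge before the data were examined. Words of 8 bases present in at least 10 windows were found on 2L and 2R and tested on the other arms. In windows taken away from summits and compared with windows farther out, a word planted in 3% of windows was recovered. A word planted in 1% was not, among 13839 and 13826 words tested, and with none planted 0 words passed. These windows were not centred on summits, so the 0 does not cover words that pass through the lower GC content of summits. Of 20 simulated gene lists with no effect 1 was below the threshold, and of 20 with an effect all 20 were, each tested without adjustment. The lists with an effect all held the same numbers of genes with and without a peak. They therefore all gave the same p, and their outcome was fixed in advance. Recovery was not measured by list size or by size of effect. The 20 of 20 therefore gives no power for the lists tested, some as short as 4 genes. Gene symbols were matched to the annotation through current names and synonyms; 18 of 19 symbols of the ZAD list matched and all symbols of the other lists did.

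The genes named were fixed by a rule before the data were examined: the nearest protein-coding gene of the 20 highest peaks, Sry-alpha, Sry-beta and Sry-delta, and up to 4 genes with the highest signal in each list. Neighbouring genes that share a promoter with one of the 20 highest peaks, and N, whose intron holds one, were named after the values were seen. With 1 group there was no comparison of conditions. Alternatives covered the promoter window, the summit distance, the list length, a stricter signal threshold, each replicate alone, the background and the motif window and mismatches. Shuffled windows that keep the dinucleotides of each summit window, divergent promoters counted by gene, the arms without Y and the feature classes among distal summits were added after the data were seen.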

Results

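Binding of Sry-beta, a C2H2 zinc finger protein encoded in the serendipity gene cluster, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos. The embryos were 0 to 12 h old and came from a transgenic line in which Sry-beta carries GFP at its C-terminal end. The series holds 1 group with 2 biological replicates, numbered 2 and 4, so no groups could be compared and every spread is that between 2 replicates. The deposited peak lists give no read counts, so the depth of the libraries is unknown. The question they address is where in the embryonic genome the tagged protein was found.

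The authors' list of peaks that passed the irreproducible discovery rate (IDR) test held 3257 peaks on the dm6 assembly. Their median width was 490 bp, and 1713 of them had exactly this width. The authors' signal value of a peak ran from 169 to 12853, with a median of 292. The highest peak lay on 2L, from 3456634 to 3457766, with its summit 77 bp upstream of the transcription start site (TSS) of Sec5 (FBgn0266670), which encodes an exocyst subunit. Next came a peak 273 bp upstream of Ten-m (FBgn0004449), a teneurin gene, on 3L from 22407714 to 22408607, and a peak 100 bp upstream of mRpL43 (FBgn0034893), which encodes a mitochondrial ribosomal protein, on 2R from 23697535 to 23698489. Of the 20 highest peaks, the summits of all but 2 lay within 500 bp of a protein-coding TSS. These included the promoters of Naus, Ugt316A1, CG10274, HtrA2, CG17597, CG7639, CG31523, Snr1, pyd, Kaz, neur, HDAC3, CG14971, CG13894 and meigo. Among these genes, Snr1 encodes a subunit of the Brahma chromatin remodelling complex, neur a ubiquitin ligase of the Notch pathway and HDAC3 a histone deacetylase. The exceptions were a peak in an intron of N, the Notch receptor gene, on X from 3162162 to 3163307, and a peak in an intron of Pcif1 on 3L from 20784456 to 20785547. The N peak was 10328 bp from the nearest TSS, that of CG18508, and had a signal of 9443. The Pcif1 peak was 1167 bp downstream of its TSS and had a signal of 8450.

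The strongest peaks of the 2 replicates fell largely at the same places. Of the 3257 highest peaks of each replicate's relaxed list, 58.4% had a summit within 100 bp of a summit among the 3257 highest of the other. Random placements of the replicate 2 peaks gave 0.497% on average (permutation test, 1000 placements, one-sided p = 0.001, the smallest they can give). Because summits within each list were at least 198 bp apart, the share was the same in both directions. Among the 500 highest peaks the share was 76.2%. The signal of the IDR peaks was also related between replicates. Over the 2825 IDR peaks with a summit within 100 bp in both relaxed lists, Spearman's rho was 0.622 and Pearson's r of log10 signal was 0.819 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give). This correlation is across peaks, which are not independent replicates and were selected by the authors from the lists of both libraries. Sec5 ranked 5 in replicate 2 and 1 in replicate 4, Ten-m 12 and 2, and mRpL43 9 and 4. The neur peak ranked 87 in replicate 2 and 7 in replicate 4, while the CG14971 peak ranked 1 and 55. The CG31523 peak, which ranked 11 in the IDR list and 5 in replicate 4, had no replicate 2 summit within 100 bp; the nearest, of an overlapping peak that ranked 102, was 108 bp away.

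**Figure D1:**
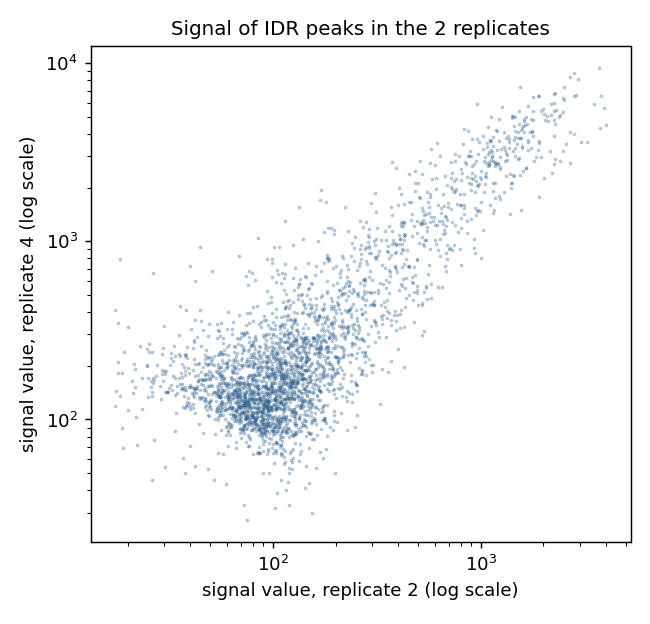
Signal value of each of 2825 IDR peaks in replicate 2 (x axis, log scale) and replicate 4 (y axis, log scale), 1 point per peak. Peaks that were high in replicate 2 tended to be high in replicate 4, with rho = 0.622.

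Sry-beta peaks lay mainly at promoters of protein-coding genes. Of the 3257 summits, 1988 (61.0%, 95% Wilson interval 59.4 to 62.7) were within 500 bp of an annotated TSS. Random positions on the same arms gave 11.5%, a 5.31-fold lower share (permutation test, 1000 placements, one-sided p = 0.001, the smallest they can give). The highest peaks of each replicate alone gave 61.8% ± 0.109 (SD, n = 2). The relaxed pooled peaks that overlapped no IDR peak had a promoter share of 24.1%. Of the promoter summits, 83.7% were upstream of the nearest TSS, at a median position of -84.5 bp from it (exact binomial test, two-sided p = 7.54e-216). At promoters without a head-to-head partner, 86.4% of 877 summits were upstream. Only 12 summits lay in coding exons (0.368%, 13.3% at random positions) and 12 in 3′ UTRs (0.368%, 5.19% at random). Introns held 797 summits (24.5%, 39.4% at random) and intergenic sequence 369 (11.3%, 27.6% at random). The 5′ UTR class beyond the promoter window held 18 summits and other transcribed sequence 61. The promoter excess alone lowers the share of every other class, so these classes were also compared among the 1269 summits outside promoters, with random positions outside promoters, a comparison chosen after the data were seen. There coding exons (0.946%, 14.9% at random) and 3′ UTRs (0.946%, 5.91% at random) were still low. Introns were high (62.8%, 44.5% at random), as was other transcribed sequence (4.81%, 2.48% at random), each of the 4 with an adjusted permutation p of 0.003 over 6 classes. Intergenic sequence (29.1%, 31.3% at random) and the 5′ UTR class (1.42%, 0.913% at random) did not differ (adjusted permutation p = 0.104 for each).

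Promoters shared by head-to-head gene pairs carried Sry-beta peaks more often than other promoters. Of 2453 TSS clusters with a pair of genes on opposite strands within 1000 bp, 870 had an IDR summit within 500 bp (35.5%). Among the other 10696 clusters 853 did (7.97%), which made the share 4.45-fold higher at divergent clusters (Fisher's exact test, two-sided p = 4.04e-235). In the replicates taken alone the ratio was 4.02 in replicate 2 and 4.76 in replicate 4. Several of the highest peaks lay between such genes, namely Sec5 and Cog3, mRpL43 and CG30183, and Snr1 and mRpL44. The peak at the pair of HtrA2 and mRpL11 had its summit 86 bp inside HtrA2. Divergent clusters hold more TSSs, and so cover more sequence, than the others. Counted by gene, 34.4% of 5052 genes with a head-to-head partner and 8.77% of 8916 without had a promoter peak (Fisher's exact test, two-sided p = 7.67e-302). This count was added after the data were seen. A summit between paired genes can count for both, so the genes are not independent in this test. Genes with more TSSs still cover more sequence, which the count does not correct. Divergent and other promoters were not compared among those with a relaxed pooled peak only, as was done for the gene lists.

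Promoter peaks were stronger than distal peaks. The median signal was 310.0 for 1988 promoter peaks and 261 for 1269 distal peaks, a ratio of 1.19 (permutation test, 100000 resamples, two-sided p = 1e-05, the smallest they can give). The ratio was 1.14 in replicate 2 and 1.25 in replicate 4.

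IDR peaks were found on 6 arms, with 639 on 2L, 553 on 2R, 654 on 3L, 790 on 3R, 25 on the fourth chromosome and 596 on X. Arm 2L held 1.14 times as many as its assembled bases predict (exact binomial test, adjusted p = 0.000838 over 7 arms). That arm has 17.2% of the assembled bases, 639 of the 3257 IDR peaks and 5754 of the 30000 pooled relaxed peaks. The excess was thus not particular to the IDR list, and the 2 lists were not tested against each other. Arms 2R, 3L, 3R, 4 and X did not pass the test, with ratios from 0.79 to 1.07. The result for 2R depended on the comparison: it was low when Y was left out (ratio 0.898, exact binomial adjusted p = 0.0135) and in replicate 4 alone (ratio 0.904, exact binomial adjusted p = 0.0205). In the higher-signal part of the list X was high (ratio 1.19, exact binomial adjusted p = 0.00277) and 2R low (ratio 0.882, adjusted p = 0.0408). No list held a peak on Y, the relaxed lists included, so the zero on Y (exact binomial adjusted p = 3.65e-35) says nothing of binding there. When the expectation was the share of protein-coding TSSs, 2L no longer differed (ratio 1.04, exact binomial adjusted p = 0.388) and 2R was low (ratio 0.831, adjusted p = 4.46e-06).

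The in vitro consensus of Sry-beta, YCAGAGATGCGCA, was more frequent at summits than beside them, at a share that depended on the mismatches allowed. With at most 2 mismatches it occurred within 50 bp of 42 of 3257 summits (1.29%) and in 20 of 6514 equal windows centred 500 bp away (0.307%), an odds ratio of 4.19 (Fisher's exact test, two-sided p = 3.52e-08). With at most 1 mismatch the shares were 0.246% and 0%, and with at most 3 they were 6.08% and 3.78%, an odds ratio of 1.65. With 2 mismatches the share was 1.72% in replicate 2 and 0.921% in replicate 4, so 1.32% ± 0.564 (SD, n = 2), and the odds ratios were 4.02 and 2.50. The related Sry-delta consensus was found at 1.75% of summits and 0.783% of flanks, and the AGAGATG core common to both at 3.19% and 0.967%. Promoter elements bound by other proteins were also found at summits; shares of different motifs do not rank them, because length and mismatches differ. The DNA replication-related element (DRE), the site of DREF, was at 3.32% of summits and 0.20% of flanks, an odds ratio of 16.6, which was 12.2 in replicate 2 alone and 7.23 in replicate 4 alone. Motif 1, a core promoter element bound by M1BP, was at 2.92% and 0.461%, an odds ratio of 6.42; in replicates 2 and 4 alone it was at 5.10% and 2.03% of summits, with odds ratios of 8.20 and 4.43. The TATA box (2.33% and 1.21%), the CTCF site (1.01% and 0.353%) and the Su(Hw) site (0.399% and 0.0768%) were also more frequent at summits. The odds ratio of Su(Hw) was 4.92, but 2.85 in replicate 2 alone and 3.19 in replicate 4 alone, and that of the shared core was 3.37, with 4.75 and 2.24. Of 13 motifs, these 8 were higher at summits in Fisher's exact test with Benjamini-Hochberg adjustment, with adjusted p from 7.13e-37 for the DRE to 0.00219 for Su(Hw). The GAGA element (1.29% and 2.46%, adjusted p = 0.000148) and the E-box (0.982% and 1.52%, adjusted p = 0.0411) were lower in the same exact test. Neither call held throughout. GAGA did not differ from flanks in replicate 2 alone (odds ratio 1.1, exact test, adjusted p = 0.515) or with 100 bp on either side of the summit (0.874, adjusted p = 0.216), and it was more frequent than in shuffled windows (2.35, adjusted p = 0.00039). The E-box stayed below 1 but did not pass the exact test in replicate 2 alone (odds ratio 0.816, adjusted p = 0.29), in replicate 4 alone (0.733, adjusted p = 0.134), in the higher-signal part of the list (0.734), with 25 bp on either side (0.603) or against class-matched relaxed peaks (0.809). The main odds ratio was 0.65. The Zelda site (0.491% and 0.645%), the initiator (8.54% and 8.23%) and the Bicoid site (2.86% and 3.38%) did not pass the test. Bicoid was lower in replicate 2 alone (odds ratio 0.715, exact test, adjusted p = 0.0165), with 100 bp on either side (0.808, adjusted p = 0.0268) and against shuffled windows (0.633, adjusted p = 0.000192). The CTCF call rested on replicate 2: in the 3257 highest peaks of replicate 4 alone the odds ratio was 1.14 (exact test, adjusted p = 0.735). Against relaxed peaks of the same promoter or distal class in place of flanks, the odds ratio was 2.66 for the Sry-beta consensus, 1.55 for the DRE and 0.854 for Motif 1 (exact test, adjusted p = 0.236). In that comparison the exact test was also not passed by the Sry-delta consensus (1.39, adjusted p = 0.0887), CTCF (1.54, adjusted p = 0.0992) and Su(Hw) (1.66, adjusted p = 0.236). None of these 3 passed the exact test in the higher-signal part of the list either (adjusted p = 0.244, 0.0866 and 0.183). Against shuffled windows the TATA box (1.17, exact test, adjusted p = 0.352) and Su(Hw) (2.35, adjusted p = 0.0625) did not pass.

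A search over all 8-mers found words of listed motifs and groups of words that were not on the list. Of 12488 words tested on 2L and 2R, 216 were more frequent at summits, and 173 of these passed again on the other arms (Fisher's exact test, Benjamini-Hochberg). The leading words on those arms were ATCGATAG, at 3.49% of 2065 summits and 0.266% of 4130 flanks, and TATCGATA, both of the DRE. They were followed by AATAGCTA (2.42% and 0.145%, odds ratio 15.9) and TAGCTAGA (2.13% and 0.0726%, odds ratio 26.0, exact test, adjusted p = 2.04e-16). GGTCACAC, part of Motif 1, was at 2.03% and 0.121%. Of the passing words, 9 held the palindrome TAGCTA. It was chosen after these values were seen. Over all arms it was in 259 summit windows (7.95%) and in 72 of 6514 flanks (1.11%), and in 7.98% and 6.91% of the highest summits of replicates 2 and 4. Summit windows had a GC content of 36.2% and flanks 44.4%. The number of passing words depended strongly on window, background and replicate, from 62 with 25 bp on either side of the summit to 453 with 100 bp. Replicate 2 alone gave 118 words, 66 of them among the 173, and replicate 4 alone gave 321, with 131 among the 173.

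**Figure D2:**
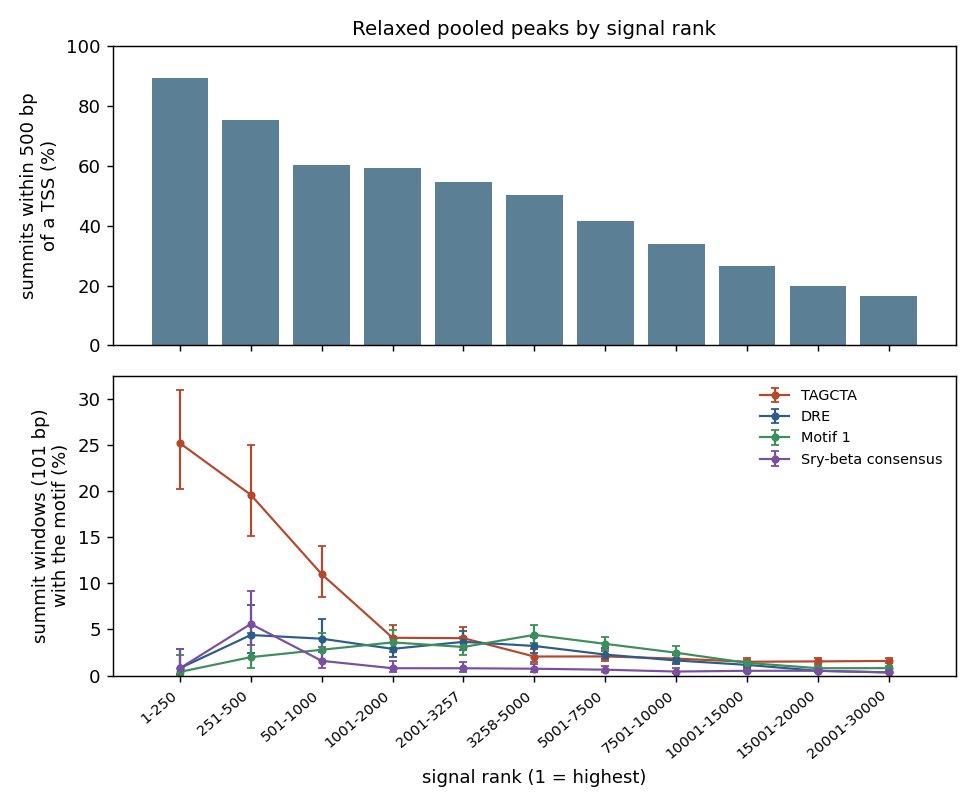
Relaxed pooled peaks in bins of falling signal rank (x axis). Bars give the percent of summits within 500 bp of a protein-coding TSS, and points give the percent of summits with each motif within 50 bp, with 95% Wilson intervals. TAGCTA fell from 25.2% of the 250 highest peaks to 1.59% of the lowest bin, while the DRE was at 0.80% of the 250 highest, 4.4% of the next 250 and 3.66% in the bin that ends at rank 3257, and fell to 0.35% in the lowest bin.

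In all, 2518 of 13968 protein-coding genes (18.0%) had an IDR summit within 500 bp of a TSS. The count was 2588 from replicate 2 alone and 2424 from replicate 4 alone, with 1842 genes in both. Of 23 gene lists fixed in advance, 9 differed from other protein-coding genes (Fisher's exact test, Benjamini-Hochberg over the lists). Genes for cytoplasmic ribosomal proteins had promoter peaks most often among the larger lists, at 59 of 92 (64.1%, exact test, adjusted p = 3.12e-21). The product of RpL24-like, a member of this list, was not checked. The list was led by RpS28b with a signal of 2793, RpL4 with 1810, RpS26 with 1651 and RpL24-like with 1095. Their summits lay 430, 422, 288 and 106 bp from these TSSs, and whether they belong to neighbouring promoters was not tested. Genes for mitochondrial ribosomal proteins followed, with 28 of 73 (38.4%, exact test, adjusted p = 0.000191), led by mRpL43, mRpL11, mRpL44 and mRpL21. The peaks at mRpL11 and mRpL44 are those next to HtrA2 and Snr1. Of 15 genes for insulator and architectural proteins 8 had a peak (53.3%, exact test, adjusted p = 0.00813), including Chro, Cp190 and the neighbours Ibf1 and Ibf2, which share a peak. Replicate 2 alone gave 10 of 15 (odds ratio 8.42) and replicate 4 alone 7 of 15 (odds ratio 4.21). Of 18 matched genes of the ZAD zinc finger list, which includes Sry-beta and Sry-delta, 8 had a peak (44.4%, exact test, adjusted p = 0.0249), with D19B, Sry-delta, grau and Zif the highest. Sry-beta, the tagged gene, and Sry-delta were among these 8 and are also in the serendipity list, so the 2 calls are not separate. The ZAD list was not tested without them. The serendipity list had 4 of 6 genes (66.7%, exact test, adjusted p = 0.0296), through only 2 distinct peaks.

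No list of patterning genes of the early embryo differed from other genes. None of 10 gap genes, 9 pair-rule genes, 8 Hox genes, 12 dorsoventral zygotic genes or 4 regulators of genome activation had a peak, and these lists were too short for a share of 0 to differ from 18.0% (exact test, adjusted p from 0.295 to 1). Of 13 maternal patterning genes vas had a peak, with a signal of 409, and of 13 segment polarity genes ci, a transcription factor of Hedgehog signalling, had one with 3074 (exact test, adjusted p = 0.62 for each list). Cell cycle genes (6 of 20, with aurA, Dp, E2f2 and Cdk2 the highest), proteasome genes (13 of 48, with Rpn11, Rpn13, Rpn5 and Prosbeta2) and heat shock genes (4 of 14, Hsp83, Hsp27, Hsc70-4 and Hsf) did not pass the test, although proteasome genes did in replicate 2 alone (17 of 48, 35.4%, exact test, adjusted p = 0.0138; 10 of 48 in replicate 4). Neuronal genes (1 of 10, elav), muscle genes (2 of 10, Mef2 and sls), germline genes (2 of 10, vas and tud) and cellularization genes (1 of 4, Sry-alpha) did not pass either. Non-coding genes had peaks less often than protein-coding genes, at 14 of 290 tRNA genes (4.83%, exact test, adjusted p = 3.91e-10), 11 of 269 snoRNA genes (4.09%, adjusted p = 1.64e-10) and 0 of 32 snRNA genes (adjusted p = 0.0132). A gene counts through any of its TSSs, and their number per gene was not corrected for. Several of the snoRNA peaks are also promoter peaks of ribosomal protein genes, and a tRNA gene shares the peak of tud. The snRNA list did not pass in replicate 2 alone, with 4 of 32 (12.5%, exact test, adjusted p = 0.673). With the higher-signal peaks it was still 0 of 32, against 10.3% of protein-coding genes (exact test, adjusted p = 0.182). The snoRNA list was low in each replicate alone, with 17 of 269 in replicate 2 (6.32%) and 9 in replicate 4 (3.35%). With a window of 1000 bp, 46 of 269 snoRNA genes had a peak (17.1%) against 20.1% of protein-coding genes (exact test, adjusted p = 0.437). None of 111 histone genes had a peak (exact test, adjusted p = 2.28e-09), and none had one in the relaxed pooled list either. The histone list is among the 9 lists that differed, but without any relaxed peak its 0 says nothing of binding there. When only genes with a relaxed pooled peak at the promoter were compared, only the cytoplasmic ribosomal protein and tRNA lists passed. The adjusted p of the exact test was then 0.0731 for the serendipity list, 0.351 for ZAD genes and 0.277 for both the insulator and mitochondrial ribosomal protein lists. The odds ratio fell from 3.69 to 1.95 for ZAD genes, from 5.17 to 2.55 for insulator genes and from 2.87 to 1.61 for mitochondrial ribosomal protein genes. For snRNA genes it changed little, from 0.0699 to 0.0778 (exact test, adjusted p = 0.0731). For snoRNA genes it moved from 0.202 to 0.471 (exact test, adjusted p = 0.0757). For the serendipity list it rose from 8.20 to 17.5, as all 4 of its genes with a relaxed peak had an IDR peak, so the list failed the test there without a fall in the ratio, with 4 genes instead of 6.

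**Figure D3:**
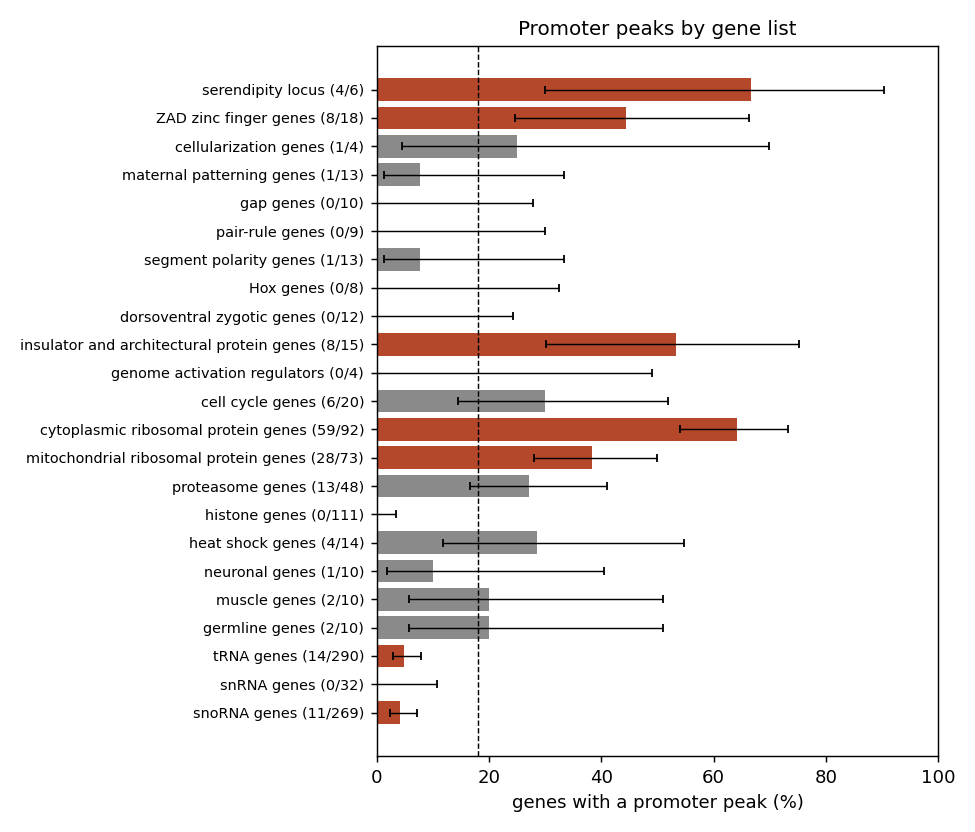
Percent of genes in each of 23 lists with an IDR summit within 500 bp of a TSS (x axis), with 95% Wilson intervals and the number of genes in brackets. Red bars are lists with an adjusted p under 0.05 and the dashed line is the 18.0% of all protein-coding genes; cytoplasmic ribosomal protein genes reached 64.1%.

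The tagged gene lies in a stretch dense in peaks. Sry-beta (FBgn0003511) and Sry-alpha (FBgn0003510) share the annotated extent from 30039719 to 30043071 on the plus strand of 3R, and Sry-delta (FBgn0003512) lies at 30043341 to 30044886. A peak from 30039458 to 30039947 had its summit 16 bp from the TSS of Sry-alpha and Sry-beta and 239 bp from that of janA. It ranked 1498 with a signal of 309. A peak from 30043171 to 30043460, 32 bp from the TSS of Sry-delta, ranked 534 with a signal of 987. Within 20 kb of Sry-beta there were 10 IDR peaks, where the mean density would give 1.06, and 7 of them were at promoters. Within 100 kb there were still 10. The highest of them, from 30056000 to 30057205, ranked 61 with a signal of 5960. The labels call the line transgenic, and reads from an added copy of the tagged gene, if it has one, cannot be separated from those of the native locus.

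**Figure D4:**
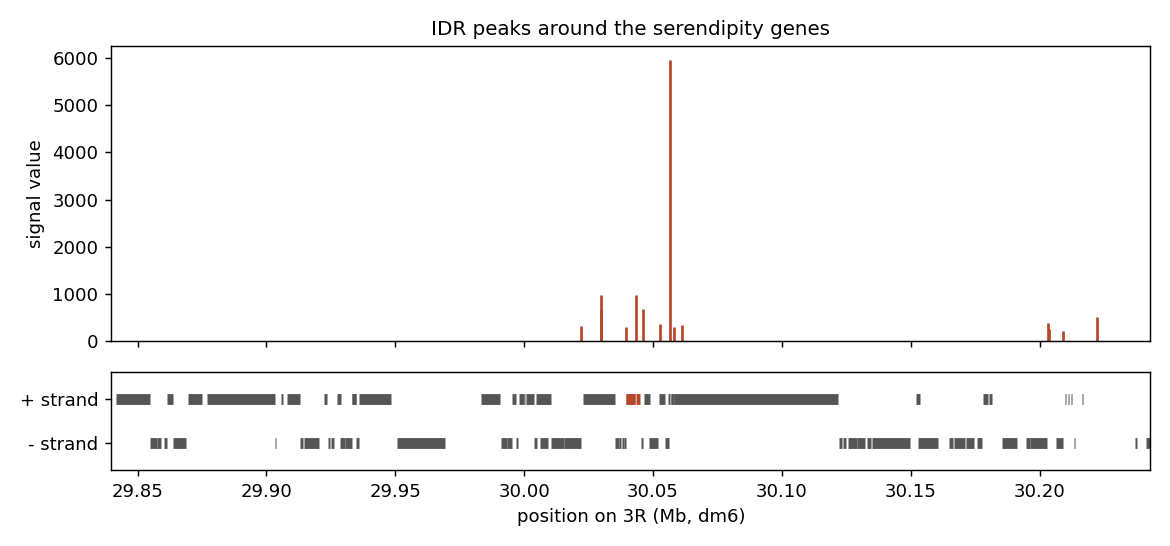
IDR peaks as lines at their summits with the authors' signal value (top, y axis) and protein-coding genes by strand (bottom) within 200 kb of Sry-beta on 3R (x axis, Mb, dm6); Sry-alpha, Sry-beta and Sry-delta are red. The 10 peaks near the genes lie between 30021889 and 30061412, and no other IDR peak lies within 100 kb.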

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

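The tests in this part were all chosen after the data were seen. The 25871 relaxed pooled peaks that overlap no IDR peak, which serve the report only as a background, stood out from random sequence. Their summits were within 500 bp of a protein-coding TSS in 24.1% of cases against 11.5% of random placements (permutation p = 0.001, the smallest they can give). Motif 1 was in 1.55% of their summit windows and 0.40% of flanking windows (Fisher's exact test, p = 6.64e-61), and the DRE in 0.997% and 0.232% (p = 9.92e-44). No explanation was tested for these shares.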

How the results depend on the processing

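Shuffled windows, divergent promoters by gene, the arms without Y and feature classes among distal summits were added after the data were seen. Over all alternatives run, the replicate overlap (44.0% to 76.2%), the replicate correlation (0.601 to 0.699), the promoter share (51.2% to 68.5%), the divergent promoter ratio, the Sry-beta consensus share and the ratio of promoter to distal signal stayed past their threshold in the same direction. Merging summits within 100 bp changed nothing, because no 2 summits of the IDR list are that close. The higher-signal part of the list held 1629 peaks, with 1434 genes. In it 4 arms, high or low (2L, 2R, X and Y), and 5 motifs higher at summits were past the threshold. GAGA was past it on the low side (odds ratio 0.37, exact test, adjusted p = 0.000203). The arms were 1 with TSSs as the expectation, and from 2 to 3 without a replicate, Y again included. As no list held a peak on Y, its part in these counts says nothing of binding. Motifs higher at summits were 4 against class-matched relaxed peaks. GAGA (odds ratio 0.582, exact test, adjusted p = 0.00224) and the initiator (0.833, adjusted p = 0.0211) were lower there. Passing words numbered 62 with 25 bp on either side of the summit, 453 with 100 bp, 66 against class-matched peaks and 93 against shuffled windows, and from 118 to 321 without a replicate; 52 of the 66 and 52 of the 93 were among the 173. Gene lists past the threshold fell to 2 when only genes with a relaxed peak were compared. Within 5 kb of Sry-beta there were 3 peaks. The cause of these changes was not tested, apart from the smaller number of peaks or genes in some.

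Several classes, motifs and arms and some lists changed direction, and apart from introns, GAGA and Motif 1 none had been called before. Among distal summits the ratio turned for introns (1.41), other transcribed sequence (1.94) and 5′ UTRs (1.55), and the intergenic class was no longer past the threshold (0.93). Odds ratios turned for GAGA (from 0.498 to 1.1 without a replicate, and 2.35 against shuffled windows, exact test, adjusted p = 0.00039), Zelda (1.07 with 25 bp on either side and 1.08 against shuffled windows) and the initiator (0.942 without replicate 2, and 0.833 against class-matched peaks, exact test, adjusted p = 0.0211). Against class-matched peaks they also turned for Motif 1 (0.854) and Bicoid (1.01). Arms turned without replicate 4 (3L 1.00, X 0.991) and with TSSs as the expectation (3L 1.04, arm 4 1.04). Odds ratios of lists crossed 1 with the higher-signal peaks (maternal patterning 1.05, segment polarity 1.05, neuronal 1.38), without a replicate (segment polarity from 0.527 to 1.03, germline 0.752, neuronal 1.29), with a 1000 bp window (genome activation 1.71, neuronal 1.17) and among genes with a relaxed peak (neuronal 1.17, muscle 0.883, germline 0.883). Among these the shares themselves turned only for germline and neuronal genes without a replicate, genome activation, muscle, and germline among genes with a relaxed peak; the other odds ratios crossed 1 through the 0.5 added to each cell. No paired analysis was possible because there is a single group. Unknown depth leaves open how many weaker sites were missed.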

Other observations

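The tests of shuffled windows, of promoter peaks inside and outside the IDR list and of signal by motif were chosen after the results were seen, as were the word TAGCTA and the count of copies at random sites; the bounds of the other tests below were written before their results.

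IDR peaks with TAGCTA or the Sry-beta consensus had a higher median signal than the rest. The median signal was 846 for the 259 IDR peaks with TAGCTA at the summit and 283 for the rest, and 745 for the 42 peaks with the Sry-beta consensus against 290.1 (permutation tests, adjusted p = 2e-05 for each over 4 motifs). Both were held by 2 peaks, and no expected number was computed for this overlap. Peaks with the DRE had a median of 282 and those with Motif 1 of 260, and neither differed from other peaks (adjusted permutation p = 0.59 and 0.23). DRE peaks were promoter peaks in 97.2% of cases, Motif 1 peaks in 93.7%, TAGCTA peaks in 69.9% and Sry-beta consensus peaks in 50%.

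TAGCTA was in 112 of the 500 highest peaks (22.4%), with 4.1% at ranks 1001 to 2000, while the Sry-beta consensus was in 16 (3.2%), with 0.80% of the first 250 and 5.6% of the next 250. The AT-rich base composition of summits accounts for part of the excess of TAGCTA but not for all of it: dinucleotide-shuffled copies of the same windows held it at 2.78%, above the 1.11% of flanks and below the 7.95% of summits, an odds ratio of 3.02 (Fisher's exact test, p = 4.21e-29). Whether copies of a repeated element contribute could not be decided: 0% of the 259 windows shared a 25-base stretch around the word with another IDR peak, but none had a copy anywhere in the genome, against 18.7% of 1000 random TAGCTA sites, and diverged copies were not searched. The word was not a general feature of promoters, being in 9.10% of promoter summits in the IDR list and 1.64% of promoter summits outside it, an odds ratio of 6.00 (Fisher's exact test, p = 2.37e-47). The word may belong to a site bound by the tagged protein or by a partner; no group of the design bears on this, and neither was tested.

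Motifs of other proteins differed between the replicates. Any of the DRE, Motif 1 and CTCF sites was at 11.1% of the 3257 highest summits of replicate 2 and 4.88% of those of replicate 4, a ratio of 2.26. A candidate source is that the lists hold different peaks: among the 1355 peaks of each replicate with no partner in the other, 27.9% and 18.1% held such a site within 250 bp, a ratio of 1.54 (Fisher's exact test, p = 1.5e-09), above the bound of 1.5 set for this source. Less exact summits in replicate 4 stay open, because in the 1902 shared peaks the ratio was 1.3 (exact McNemar test, p = 0.000409), which lies at the bound of 1.3 set beforehand and not past it. As the shared peaks gave 1.3 within 50 bp and all peaks 2.26, the peaks of 1 replicate only differed by more than 2.26 there. The 1.54 within 250 bp thus understates their difference close to the summit and does not set less exact summits aside. The design has no group that could separate a biological difference from these sources.

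The IDR peaks near Sry-beta form an island of 39.5 kb, with 191 kb on the left and 142 kb on the right free of IDR peaks. Of all stretches of this window length, 43353 bp, at 5 kb steps, 0.0711% held 10 or more peaks. Gene density alone does not account for it, as 7 of 10 promoter clusters within 20 kb had a peak against 13.1% elsewhere. The ratio was 5.36 (Fisher's exact test, p = 5.48e-05), and from 20 to 100 kb 0 of 15 clusters had a peak. The test compares shares per cluster and not clusters per kb, so gene density may still account for part of the crowding. It also did not separate divergent clusters, of which 35.5% had a peak over all arms. Extra copies of the region on the transgene may raise its signal, but the test of this could not decide: relaxed distal peaks were 0.769 times as dense within 20 kb as from 20 to 100 kb in the pooled list (95% exact interval 0.229 to 2.06), 1.44 times in replicate 2 and 1.12 times in replicate 4. The bounds were set beforehand for the ratio itself, and 0.769 lies under the lower one of 1.2, but the interval, weighed only after the result was seen, spans both, and peaks raised above the IDR threshold are missing from this count. The extent of the transgene's genomic insert is not given in the sources used here, so extra copies and binding at the native locus cannot be told apart.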
